A study of Mus musculus with 2 samples.

How the data were processed

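H3K36me3 was measured by chromatin immunoprecipitation and sequencing in mouse midbrain at embryonic day 13.5, with fragments of 300 to 500 bp per the labels, in 2 biological replicates that were treated as 1 group. Both samples name the same strain and tissue, and the labels call them separate biological replicates, each of which combines technical replicates. The 4 peak lists were used as deposited: 1 per replicate, 1 called on both replicates together and 1 of replicated peaks. Per the text deposited beside the lists, reads were aligned to mm10, each replicate list derives from that replicate's alignments, and the replicated list derives from the other 3. Each of the replicate and pooled lists also names 1 source file that is not described there, and the replicate 1 and pooled lists name 1 more that the replicate 2 list does not. The labels name a possible control experiment, which was not among the files used. The aligner, the peak caller and their settings are not given in the sources used here.

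Each list gives, in the narrowPeak layout named in the text deposited beside it, the fold enrichment of every peak as a linear ratio over background, and the −log10 of its p-value and q-value. These deposited values were used only to describe, rank or filter peaks within a list. The lowest −log10 p was 2.00 in replicate 1, 2.03 in replicate 2 and 2.01 in the pooled list. The lists therefore reach down to weak peaks, and 89.9% of replicate 1 peaks and 92.4% of replicate 2 peaks had a −log10 q of at least 2. Median fold enrichment was 3.10 in replicate 1 and 3.46 in replicate 2, median peak width 355 and 369 bp, and covered length 117.6 and 103.8 Mb (mean 110.7 ± 9.76, SD, n = 2), or 122.2 Mb in the replicated list. Read numbers are not part of a peak list. The depth of each replicate is therefore unknown, a gene without a peak is one where none was called, and the number of peaks moves with depth and with the threshold of the call.

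The annotation was GENCODE mouse release 21 on GRCm38, the assembly that mm10 names, and no peak ended beyond its chromosome. Genes were protein-coding, at least 1 kb long and on the 19 autosomes or X, and a symbol with several gene identifiers was counted once, which left 21033 genes. Coverage is the percentage of the gene span, introns included, inside peaks. A gene was called covered at 10% or more by replicated peaks. Base pairs were assigned to 1 class each, in the order promoter (1 kb either side of a transcription start of a basic coding transcript), 5′ UTR, coding exon, 3′ UTR, intron and intergenic. The profile along the gene used 10 equal bins in genes of at least 5 kb. For exons, the transcript with the most exonic bases was taken per gene, and intron windows of the exon's length, 500 bp away on both sides, had to be free of annotated coding-gene exons.

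Overlap of the replicates (at least 1 bp) was compared with 1000 circular shifts of one list, and covered genes and genomic classes with 100 shifts, each of at least 1 Mb and leaving out the first 3 Mb of each chromosome. Position and exon ratios were tested over the 20 chromosomes by an exact two-sided sign-flip test. Chromosomes are not biological replicates, so its p-value describes agreement between chromosomes within these 2 libraries and not the spread between embryos. For 28 gene lists, the median coverage was compared with 10000 random lists matched on 20 classes of gene length (two-sided), and covered members were compared with all other genes by Fisher's exact test. Both sets of p-values were adjusted over the 28 lists by the Benjamini-Hochberg method. Fisher's test does not match gene length, so the number expected from length-matched lists is plotted beside it. These tests, the lists, the thresholds and the alternative settings were set before the data were examined. The alternatives were a −log10 q of at least 2, other thresholds of overlap, gene length and coverage, pooled peaks, each replicate's own list alone, unmatched random lists (2000 draws), gene spans without the first 1 kb, windows 1000 bp away and other merging gaps. The mean in place of the median was added after the data were seen.

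Genes named in the text follow a rule fixed with them: in each list the 2 members with the highest and the 2 with the lowest coverage (ties in alphabetical order, left out where the whole list was at 0), the 10 genes of at least 5 kb with the highest coverage, the 5 with the largest difference in either direction between replicates, and the 5 longest domains and 5 peaks of highest fold enrichment. With 1 group there was no comparison of groups, and the values of both replicates are given. Differences of gene lists between the 2 replicates were set against random lists of genes matched on coverage, which describes these 2 libraries, since genes are not replicates.

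The functions were tested on simulated data on the real gene models. Coverage differed from a count base by base in 0 of 2000 windows. A planted list of 25 genes was found with a permutation p of 0.0016, and of 200 random lists 3.0% had a p under 0.05 with either test. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Base content and repeat masking came from the RefSeq sequence of GRCm38. Peaks on chromosome Y and on scaffolds were left out of the gene analyses.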

Results

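Trimethylation of lysine 36 on histone H3 (H3K36me3), a mark laid down on the bodies of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing in mouse midbrain at embryonic day 13.5. The labels describe midbrain tissue of the B6NCrl strain, pooled from male and female embryos, as 2 biological replicates of 1 group. There was no second group, so the comparisons made were between the replicates, between parts of the genome and between sets of genes. The deposited lists held 193460 peaks for replicate 1 and 167667 for replicate 2 (mean 180564 ± 18238, SD, n = 2). A list called on both replicates together held 193396 peaks, and a list of replicated peaks held 128364. No list gives read numbers, so the sequencing depth is unknown. Coordinates are those of mm10, counted from 1, and a pair of values in parentheses after a gene's coverage gives replicate 1 and then replicate 2.

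The same genes carried the mark in both replicates. Of 21033 protein-coding genes of at least 1 kb on the autosomes and X, 8460 had at least 10% of their span inside replicate 1 peaks and 8001 inside replicate 2 peaks, and 7918 of these genes were shared. Splicing factor Sf3a1 had 89.7% and 89.8% of its span inside peaks in the 2 replicates, and the transcription cofactor Trrap had 90.6% and 90.3%. Among genes of at least 5 kb, those with the largest excess in replicate 1 were B9d1, which acts in cilia (46.0% against 15.8%), the DNA glycosylase gene Neil1 (40.2% against 13.2%), Chrd, which encodes the BMP antagonist chordin (31.6% against 7.80%), Thap3 (28.7% against 5.41%) and the riboflavin transporter gene Slc52a2 (59.7% against 36.4%). The largest excess in replicate 2 was at Tmem199 (54.0% against 36.3% in replicate 1), Atp5g2, which encodes a subunit of ATP synthase (51.6% against 33.9%), Gm49405 (17.0% against 0%, with 76.7% of its span shared with other coding genes), Emg1, which acts in ribosome assembly (48.1% against 32.9%), and Fam131b (40.3% against 25.9%).

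Across genes, which are not independent replicates, the coverage in the 2 replicates had a Pearson r of 0.988 and a Spearman rho of 0.973. Among the 8416 genes covered by replicated peaks, coverage was higher in replicate 1 for 81.6%, by a median of 3.05 percentage points, and the SD between replicates was 4.29 points. At the level of single peaks, 69.5% of replicate 1 peaks were overlapped by at least 1 bp by a replicate 2 peak, and 83.3% of replicate 2 peaks by a replicate 1 peak. When one list was moved along each chromosome 1000 times, the mean shares were 6.65% and 7.62%. The base-pair Jaccard index was 61.9% against a mean of 2.40% after moving (one-sided permutation p = 0.001 for each of the 3 measures, the smallest that 1000 shifts can give). The peaks without a partner were narrower and weaker than shared peaks. Their median width was 233 bp in replicate 1, against 474 bp for shared peaks, and their median fold enrichment 2.72 against 3.44. In replicate 2 these values were 229 bp against 428 bp and 2.95 against 3.61. All of the 1000 peaks of lowest p-value in each replicate were overlapped in the other.

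**Figure D1:**
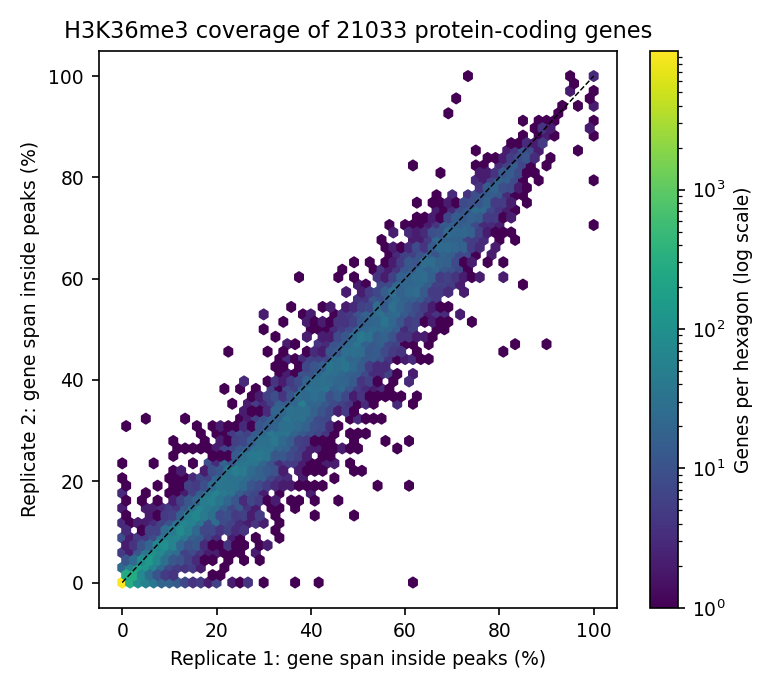
Share of each gene's span inside peaks, in per cent, for 21033 protein-coding genes in replicate 1 (x axis) and replicate 2 (y axis), with the number of genes per hexagon on a log colour scale and the line of equal values dashed. The points follow the line (Pearson r of 0.988) and lie mostly on the replicate 1 side, by a median of 3.05 percentage points among covered genes.

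The replicated list held the broad and strong part of the pooled list. All of its 128364 rows were rows of the pooled list, of which it kept 66.4%. Of the kept peaks, 84.3% shared at least 50% of their own or the partner's width with a single peak in both replicates, and 0 of the 65032 dropped peaks did. The other kept peaks did not meet this overlap, and what kept them is not given in the sources used here. The median fold enrichment was 3.41 for kept and 2.41 for dropped peaks, and the median width was 575 bp and 218 bp.

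Replicated peaks lay on 8416 of the 21033 protein-coding genes (40.0%), counting genes with at least 10% of the span inside peaks, and 10095 genes (48.0%) had no base inside a peak. Among genes of at least 5 kb, the most completely covered were Prss53 on chromosome 7 (127885841–127890970; 100% of the span), Gigyf1, which acts in growth factor signalling and translation (chromosome 5, 137518548–137527935; 98.8%), Pla2g4b (chromosome 2, 120033417–120043030; 95.3%), Trrap (chromosome 5, 144767732–144859778; 93.7%) and Ecm1 (chromosome 3, 95734147–95739569; 93.6%). These were followed by the histone H2B ubiquitin ligase gene Rnf40 (chromosome 7, 127588767–127604799; 93.0%), 1700109H08Rik (chromosome 5, 3571566–3584356; 92.7%), Sf3a1 (chromosome 11, 4160350–4182541; 92.5%), the Integrator subunit gene Ints1 (chromosome 5, 139751282–139775674; 92.4%) and Celsr3, a cadherin of axon tracts (chromosome 9, 108826320–108852969; 91.9%). Other coding genes share 95.5% of the span of Prss53 and 100% of the spans of Gigyf1 and Pla2g4b, so peaks there cannot be assigned to 1 gene. Ecm1 was the least alike between the replicates of these 10 genes (74.3% and 51.2%).

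The median coverage of the covered genes was 42.5%, and 3362 genes had at least 50%. In 100 circular shifts of the peaks the number of covered genes averaged 2674 and reached at most 2919 (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). Of the covered genes, 7911 passed the 10% mark in both replicates' own lists. Short genes were covered less often. With the genes split by length into 4 classes of equal number, 25.3% were covered in the shortest class (median length 4.20 kb), then 45.1%, 52.5% and 37.2% in the longer classes. Genes that share bases with another coding gene were covered more often (55.5%) than those that share none (35.8%). A peak on shared bases counts for each of the genes there, so the measure itself can raise the share of overlapping genes.

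The mark was a mark of gene bodies and was sparse at promoters and between genes. Introns held 75.6% of the replicated-peak base pairs, coding exons 10.4%, 3′ UTRs 7.07%, intergenic sequence 5.81%, promoters (within 1 kb of a transcription start) 0.977% and 5′ UTRs outside promoters 0.123%. Relative to their share of the genome, coding exons were represented 9.10-fold, 3′ UTRs 5.97-fold, 5′ UTRs 3.57-fold and introns 2.12-fold, while promoters stood at 0.483 and intergenic sequence at 0.0969 of their share. Each class lay outside the range of the 100 circular shifts (two-sided permutation p = 0.0198, the smallest possible), and 94.1% of the peak base pairs were inside the genes tested.

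Coverage rose from the 5′ to the 3′ end of genes. In 7660 covered genes of at least 5 kb, cut into 10 equal bins, the mean share inside peaks was 5.42% in bin 1, 47.0% in bin 5, 64.9% in bin 9 and 62.6% in bin 10. The first 20% of the span averaged 12.3% and the last 20% averaged 63.7%, a log2 ratio of 2.38 ± 0.26 (SD over 20 chromosomes), above 0 on 20 of 20 chromosomes (exact two-sided sign-flip p = 1.91e-06, the smallest that 20 chromosomes allow). The 2 replicates gave 11.9% and 59.8%, and 10.2% and 56.0%. In all 17675 genes of at least 5 kb the means were 5.61% and 29.0%. Tests over chromosomes, here and for exons, describe these 2 libraries, since chromosomes are not biological replicates.

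**Figure D2:**
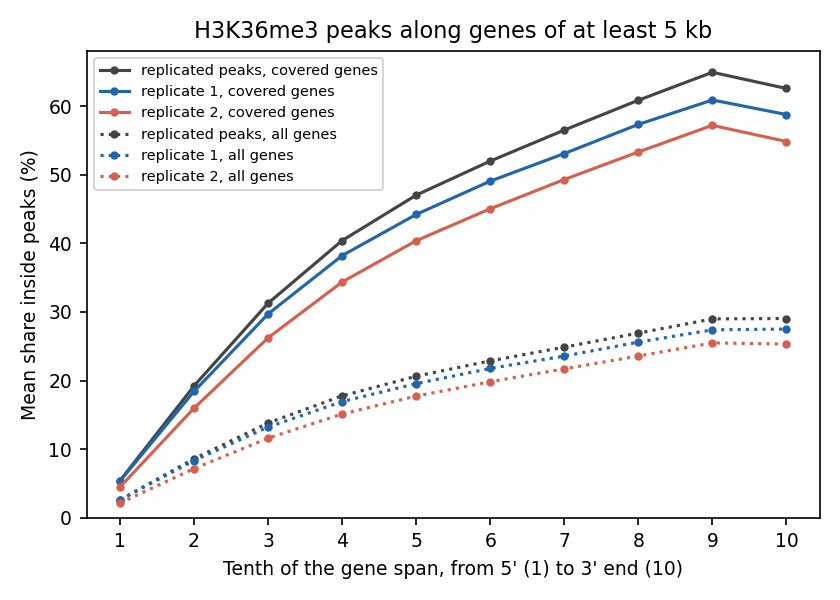
Mean share of each of 10 equal bins of the gene span inside peaks, in per cent, from the 5′ end (1) to the 3′ end (10), for covered genes (solid lines) and all genes (dotted lines) of at least 5 kb, with replicated peaks in grey, replicate 1 in blue and replicate 2 in orange. In covered genes the replicated-peak line climbs from 5.42% in bin 1 to 64.9% in bin 9.

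Internal exons of covered genes were covered more than the introns around them. Peaks held 71.6% of the bases of 38966 internal exons and 52.7% of the bases of windows of the same length 500 bp away on both sides. The log2 ratio was 0.45 ± 0.055 (SD over 20 chromosomes), above 0 on 20 of 20 chromosomes (exact two-sided sign-flip p = 1.91e-06). Replicate 1 alone gave 68.2% and 49.0%, and replicate 2 alone 64.1% and 44.9%. Exons also differed from the windows in base content, with a mean GC of 48.5% against 43.3%. Among 1380 exon and window pairs of equal GC (within 2 percentage points) that held no repeat-masked base, exons had 72.0% and windows 69.3% inside peaks, and the log2 ratio averaged −0.000286 ± 0.20 over chromosomes (13 of 20 above 0, exact sign-flip p = 0.995).

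All 26 spliceosome components and splicing regulators were covered, with a median of 64.7% of the span, from Sf3a1 (92.5%; 89.7% and 89.8%) and Snrnp200 (90.2%; 88.7% and 86.7%) down to Srsf2 (18.1%; 22.2% and 16.8%) and Ptbp2, the neural polypyrimidine tract protein (15.2%; 16.3% and 14.02%). Other coding genes share 100% of the span of Srsf2, so its peaks cannot be assigned to 1 gene. Of 22 subunits of the BAF chromatin-remodelling complex, 20 were covered (median 62.5%), with Brd9 at 87.7% and Smarcc2 at 86.4%, and the neural subunit gene Dpf3 at 1.17% and Arid1b at 8.74%. Cytosolic ribosomal protein genes (64 of 78, median 47.5%) reached 84.0% at Rps15a and 80.3% at Rps3, with 0% at Rpl30 and Rpl10l. Genes with names that start with Nduf (40 of 46, median 40.5%) included Ndufa10 at 82.6% and Ndufa9 at 75.9%, and 0% at Ndufa1 and Ndufa4l2. Many of them serve mitochondrial complex I, but the list was drawn by name and not every member is a subunit of it.

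Writers, erasers and readers of H3K36 methylation themselves were covered in 21 of 23 cases (median 46.2%). The demethylase gene Kdm4a had 91.2% (89.4% and 88.1%) and Glyr1 90.2%, while Phf19 had 0% and Smyd2 8.78%. Zinc finger genes named Zfp were covered in 288 of 391 cases (median 33.1%), with Zfp869 at 93.9% and Zfp2 at 88.1%, and 0% at Zfp114 and Zfp174. Cell cycle genes were covered in 21 of 22 cases (median 38.8%), with the replication helicase genes Mcm5 at 76.5% and Mcm2 at 71.0%, the checkpoint kinase gene Bub1 at 15.1% and the cyclin gene Ccnb1 at 0%. Polycomb subunit genes were covered in 18 of 21 cases (median 30.3%), with Ring1 at 71.9% and Phc1 at 70.5%, Cbx7 at 5.09% and Pcgf5 at 0%. Widely used housekeeping genes were covered in 17 of 22 cases (median 37.4%), with Eef2 at 85.1% and Polr2b at 81.0%, B2m at 0% and the X-linked Hprt at 3.38%.

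Neuronal differentiation genes were covered in 15 of 22 cases, against 7.40 expected from genes of the same length, with a median coverage of 14.9% against 1.33% in length-matched random lists (permutation adjusted p = 0.064). Elavl3, a neuronal RNA-binding protein gene, had 50.3% (45.4% and 46.8%), with 42.3% of its span shared with other genes, and the intermediate filament gene Ina had 43.7% (41.5% and 41.9%). Rbfox3, which encodes the mature-neuron antigen NeuN, had 0.106% and Nhlh1 had 0%. Neural progenitor markers were covered in 8 of 20 cases, with the RNA-binding protein gene Msi1 at 67.3% (66.4% and 63.5%) and Vim at 47.1% (39.9% and 35.1%), and 0% at Ascl1 and Fabp7. Axon guidance genes were covered in 6 of 25 cases, with the plexin genes Plxnb1 at 85.2% and Plxna1 at 84.9%, Sema3a at 0% and Robo2 at 0.177%. Transmitter genes were covered in 3 of 15 cases, among them the GABA transporter gene Slc6a1 at 45.7% (40.6% and 37.6%) and Gad1, which makes GABA, at 18.5% (18.4% and 13.6%), with 0% at Chat and Dbh.

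Transcription factors that pattern the midbrain were sparsely covered. Of 22 such genes only Lhx1 passed 10%, with 12.9% (11.8% and 6.81%), and Otx2 had 9.58% (8.44% and 4.39%), while En1 and Foxa1 had 0%. The count was 4 with pooled peaks, 2 with replicate 1 peaks alone and 0 with replicate 2 peaks alone. None of 13 dopaminergic genes was covered: Slc18a2, the vesicular monoamine transporter gene, had 1.29%, and Aldh1a1 and Ddc had 0%. Some genes, En1 among them, belong to both the midbrain and the dopaminergic list, so the results of these lists are not independent. Of 19 telencephalic factors, of which 1 was covered (0 with replicate 2 peaks alone), Lhx2 had 14.1% (12.1% and 8.46%) and Bcl11b 4.71%, with 0% at Arx and Dlx1. All 39 Hox genes had 0%, in the replicated list and in each replicate.

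Marker genes of tissues outside the brain were mostly not covered either, nor were those of its vessels and microglia. No member was covered among 14 endothelial and pericyte markers (highest Pdgfrb, 5.37%), 13 mesenchymal markers (0% in each), 16 muscle genes (highest Ttn, 2.70%), 16 hepatocyte genes (highest Hnf1a, 7.39%), 14 keratinocyte genes (highest Col17a1, 1.24%) and 15 germ cell genes (highest Dazl, 2.15%). No olfactory receptor gene, a marker of sensory neurons outside the brain, was covered among 1029 (highest Olfr543, 5.84%). Of 18 microglial and blood markers only Cx3cr1 was covered (17.4%, with 53.2% of its span shared with other genes), followed by Csf1r at 9.31%.

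Glial markers, which belong to the neural lineage, were covered in 2 of 15 cases, Cnp (78.7%, with 53.0% of the span shared with other genes) and Mog (15.6%), and had 0% at Aldh1l1 and Aqp4. Imprinted genes were covered in 9 of 21 cases, from Nnat (82.9%, its whole span inside another gene) and the maternally expressed Igf2r (61.5%; 54.4% and 51.0%) to 0% at Asb4 and Cdkn1c. Clustered protocadherin genes, whose spans overlap each other, were covered in 21 of 56 cases, with Pcdhga3 at 52.3%, Pcdhga2 at 52.0% and 0% at Pcdhb1 and Pcdhb10.

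In Fisher's exact test of covered members against all other genes, 10 of the 28 lists held more covered genes at a Benjamini-Hochberg adjusted p under 0.05: ribosomal proteins (adjusted p = 3.3e-13), splicing (3.1e-10), Nduf (3.2e-10), Zfp (6.6e-41), cell cycle (2.4e-07), H3K36 machinery (1.5e-06), BAF (3.0e-06), Polycomb (6.1e-05), housekeeping (0.0013) and neurons (0.011). Another 13 held fewer: olfactory receptors (3.4e-235), Hox (1.7e-08), midbrain factors (0.00071), muscle and hepatocytes (0.00088 each), germ cells (0.0014), endothelium, telencephalic factors and keratinocytes (0.0023 each), dopaminergic, microglia and blood, and mesenchyme (0.0035 each) and glia (0.044). Neural progenitor (1.0), axon guidance (0.18), transmitter (0.21), imprinted (0.86) and protocadherin lists (0.85) did not pass. With replicate 2 peaks alone, Fisher's exact test no longer called neurons (13 covered, adjusted p = 0.062) or glia (2 covered, adjusted p = 0.075). Against 10000 random lists of the same size and gene lengths, the median coverage of 6 lists was higher: splicing, H3K36 machinery, BAF, Zfp, ribosomal proteins and Nduf (two-sided permutation adjusted p = 0.00093 each). No list had a lower median at this threshold. For each list but Zfp the lower end of the random range was itself 0, so this test could not call a lower median there. Genes of 1 list are not independent replicates, and these tests describe the lists within these 2 libraries.

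**Figure D3:**
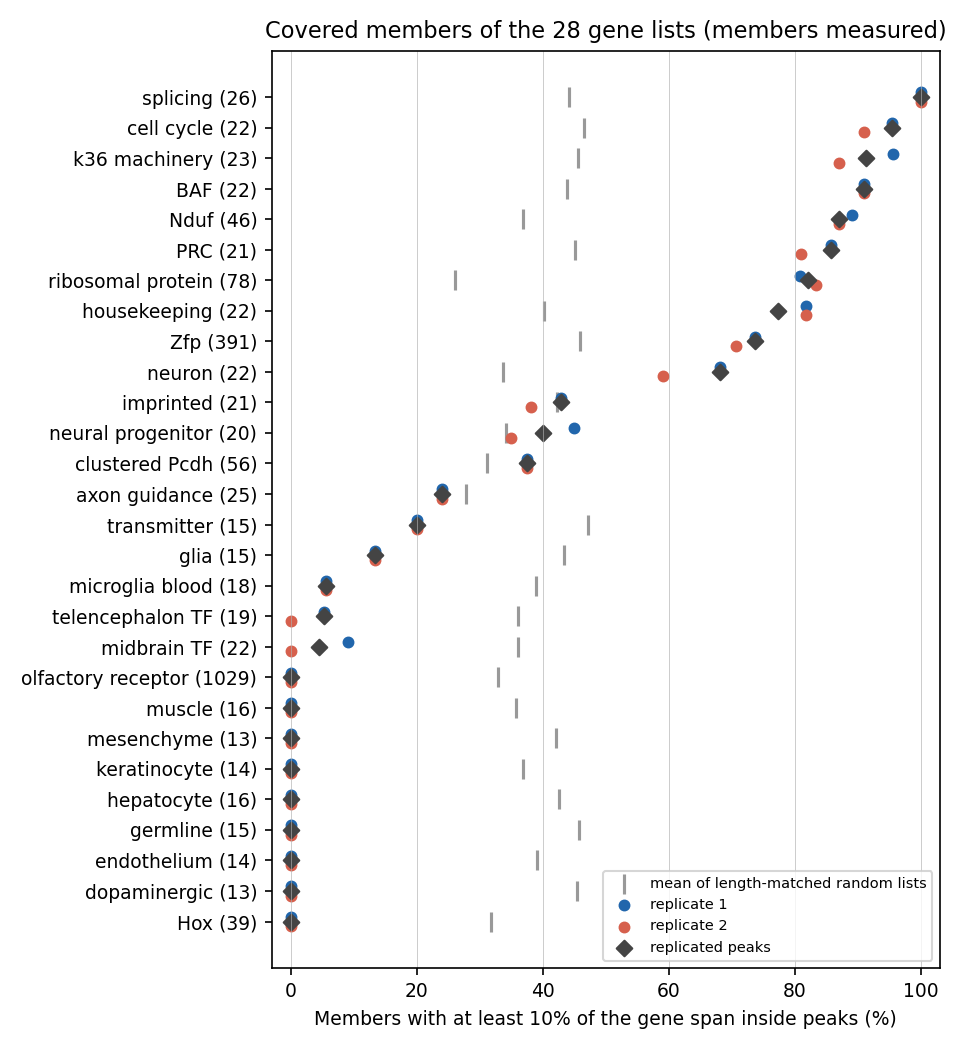
Share of the members of each of 28 gene lists with at least 10% of the gene span inside peaks, in per cent, with replicated peaks as diamonds, replicate 1 in blue, replicate 2 in orange and the mean of length-matched random lists as a grey bar (members measured in parentheses). Splicing genes stand at 100% and Hox genes at 0%.

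Genes on chromosome X were covered less often than genes on any autosome. Of 877 X-linked genes, 131 were covered (14.9%; 15.6% and 13.6% in the 2 replicates), against 327.4 expected from random lists of genes of the same length. On the autosomes the share ran from 31.3% on chromosome 14 to 51.7% on chromosome 8. Covered X-linked genes had a median coverage of 27.2%, below each autosome, where the lowest median was 35.7% on chromosome 14. Fisher's exact test of X-linked against other genes gave p = 5.8e-61. Genes of 1 chromosome are not independent replicates, and this test describes these 2 libraries. Embryos of both sexes were pooled, so X was present in fewer copies than each autosome. Whether this made peaks on X harder to call was not tested. The median over X-linked genes was 0, as in random lists (two-sided permutation p = 1.0), whereas the mean, chosen after the data were seen, was 5.33% against 16.8% (permutation p = 0.0002, the smallest possible).

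**Figure D4:**
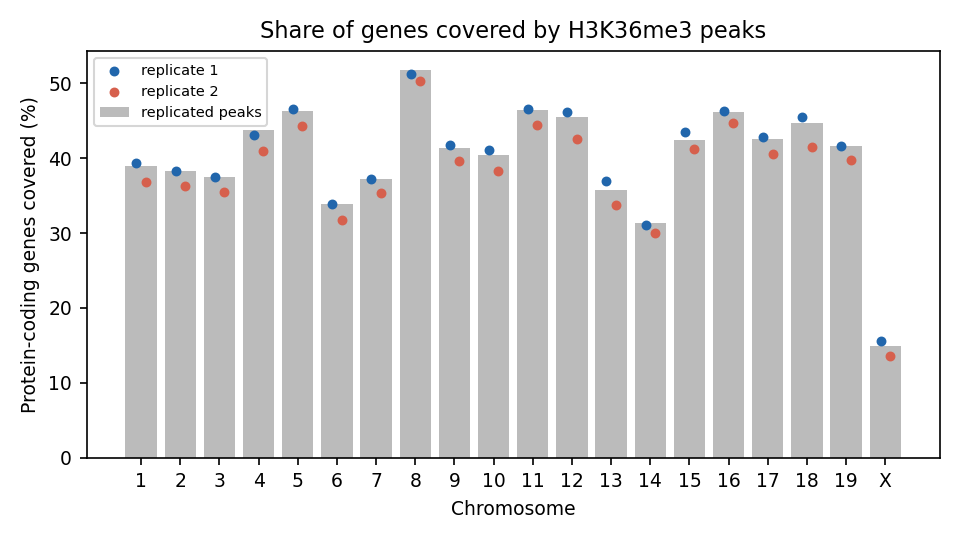
Share of protein-coding genes covered by replicated peaks on each chromosome (bars, per cent), with replicate 1 in blue and replicate 2 in orange. The X chromosome stands at 14.9%, and the autosomes lie between 31.3% and 51.7%.

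Merging replicated peaks across gaps of up to 2 kb gave 28838 domains with a median length of 2.12 kb, of which 188 exceeded 50 kb and 8 exceeded 100 kb. The longest lay over the 3′ part of Wdfy3, a gene of selective autophagy, at 101831241–101961525 on chromosome 5 (130.3 kb, 73 peaks, with 84.7% of its bases inside replicated peaks, and 80.7% and 78.0% in the replicates). It was followed by Hectd4 and Trafd1 (chromosome 5, 121253906–121383382; 129.5 kb), Vps13d (chromosome 4, 145069026–145190600; 121.6 kb), Mdn1, which acts in ribosome assembly (chromosome 4, 32661270–32778330; 117.1 kb), and the BAF subunit gene Smarcc1 (chromosome 9, 110135495–110242414; 106.9 kb). The count and lengths depend on the merging distance: 59836 domains resulted with gaps of up to 500 bp and 17883 with gaps of up to 5 kb. The median length was 1.34 kb with the peaks of replicate 1 alone and 1.63 kb with those of replicate 2 alone.

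**Figure D5:**
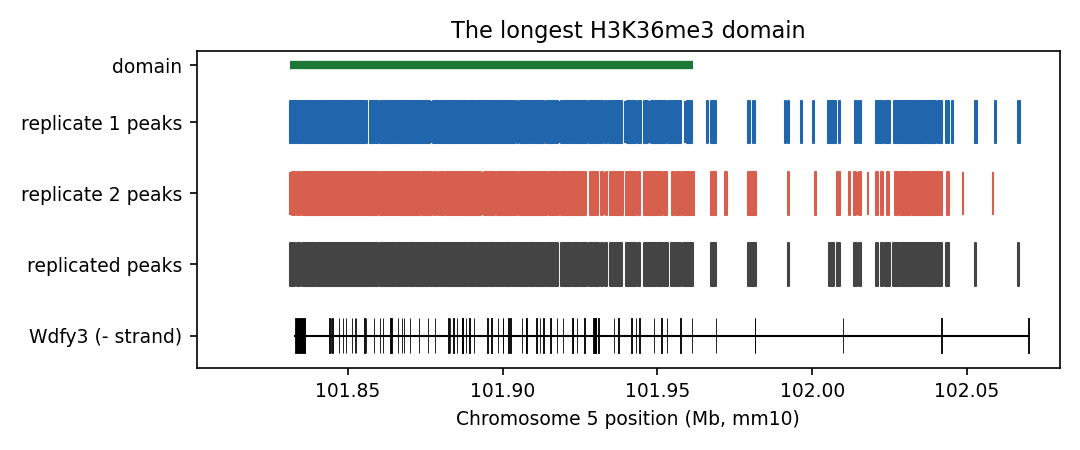
Peaks of each replicate and replicated peaks over the longest domain (green bar) and the gene Wdfy3, drawn to scale along chromosome 5 in Mb of mm10, with exons as black bars. Peaks fill 84.7% of the domain, which spans the 3′ part of the gene on the minus strand.

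The highest fold enrichments, which are the authors' own values per peak, lay in zinc finger genes. The 5 strongest replicated peaks were in Zfp810 (chromosome 9, 22276718–22281168; 19.9-fold), Zfp146 (chromosome 7, 30160639–30164381; 19.0-fold), Zfp354c (chromosome 11, 50811896–50818852; 18.1-fold), Zfp329 (chromosome 7, 12807339–12811707; 17.9-fold) and Zfp27 (chromosome 7, 29890234–29896904; 16.7-fold). The replicates' own peaks there reached 19.0 and 18.7 at Zfp810, 14.2 and 16.3 at Zfp146, and 17.2 and 11.8 at Zfp354c. The Zfp810 peak was 26.1% coding exon, 33.3% 3′ UTR and 40.0% intron, and the Zfp329 peak 37.3% coding exon and 60.2% 3′ UTR. At Zfp27, 46.5% of the peak was outside annotated coding genes.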

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

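The 3 patterns weighed here were chosen after the main results had been seen, each test and its bounds were written before its own result was seen, and the test of GC content and repeats together was added after the tests of each alone. No biological explanation was given by the design, which has 1 group, so none was tested except tissue composition between the replicates.

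Peaks were also called on sequences and genes left out of the comparisons. The replicated list held 8 peaks on chromosome Y. They include peaks at 1277135–1277363 and 1278198–1278850 in Ddx3y, a single peak at 259230–259429, and 5 peaks between 90738717 and 90745840 near the end of the chromosome. Another 20 replicated peaks lay on scaffolds outside the chromosomes. Among 7541 non-coding genes of at least 1 kb that lie at least 5 kb from any coding gene, 83 were covered, 60 of them in both replicates' own lists. Genes were taken as typed in the annotation, and some of them share bases, so the 83 are not separate regions. Gm26906, for example, lies inside Meg3. CT010467.1, typed as rRNA, and Gm42418 overlap each other on chromosome 17, and both had 0% in replicate 1. Circular shifts were not run for these counts and no control sample was among the files, so they are given without a background level.

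The excess of coverage on internal exons over nearby intron was the first pattern weighed (log2 ratio 0.45). With exon and window pairs matched within 2 percentage points of GC the ratio fell to 0.14 ± 0.082 (SD over chromosomes, 10808 pairs, 19 of 20 above 0, exact sign-flip p = 5.72e-06), and with pairs free of repeat-masked bases to 0.16 ± 0.073 (8598 pairs, 20 of 20, p = 1.91e-06), so that a smaller excess remained under either condition alone. With both conditions it was −0.000286 ± 0.20 (1380 pairs, 13 of 20, exact p = 0.995). GC content and repeats together are therefore a candidate explanation for the excess. They change how well reads are sequenced and placed. They may also go with a true difference between exons and introns, which matching would then remove. The pairs left were unlike the rest, with 69.3% of window bases inside peaks against 52.7% over all pairs. Whether a smaller true excess of exons remains stays open, since only 1380 pairs met both conditions and over them exons still had 72.0% against 69.3% inside peaks.

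The second pattern was that zinc finger genes named Zfp held 41 of the 100 replicated peaks of highest fold enrichment, in 32 genes, against 2.01% of all replicated peaks (Fisher's exact p = 1.2e-42, counted after the 5 strongest peaks had been seen). Peaks are not independent, since some of these genes held several, and the 5 strongest peaks are among the 41. Reads shared between copies identical over 31 bases are argued against. Of the 31-base words in these 41 peaks, 3.84% occurred more than once on the 21 chromosomes (bootstrap SD 0.531 over peaks), against 3.04% in the other 59 peaks of the 100. This holds for the 41 peaks as a set, since only 27 of them were under the bound of 5% and the highest reached 20.9%. Only exact words on these chromosomes were counted. Reads from near-identical copies that differ within 31 bases, or from copies absent from these chromosomes, were therefore not tested. Peak width stays open as a part of the pattern. The 2578 replicated peaks in Zfp genes were wider than other peaks (median 665.5 against 573 bp). Their median fold enrichment exceeded that of other peaks by 0.386 before and by 0.246 after matching on width (SD over 19 chromosomes 0.2495, above 0 on 17 of them). These medians are not over the 41 highest peaks, so they cannot tell whether width accounts for those. Stronger enrichment may itself widen a peak, so that matching on width could remove part of a true difference.

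The third pattern was the higher gene coverage in replicate 1: with the 167667 peaks of lowest p-value kept in each replicate, the median difference over covered genes fell from 3.05 to 1.74 percentage points and 70.5% of covered genes were still higher in replicate 1, so the number of peaks may account for part of it. Tissue composition stays open: of 14 lists with at least 5 covered members, the median difference was above that of coverage-matched random lists for Nduf (5.95 against 3.30 points) and below it for Zfp (2.29 against 3.04) and ribosomal protein genes (1.55 against 3.15; adjusted permutation p = 0.007, 0.007 and 0.02, over genes of these 2 libraries). This met the bound written for composition, which was judged too wide only after the result was seen, since these lists mark no cell type. Cell cycle genes, which follow the share of dividing cells, differed by 5.84 against 3.35 points (permutation p = 0.019, adjusted 0.068), and progenitor (3.98 against 2.95) and neuron genes (2.36 against 2.97) had an adjusted permutation p of 0.64 each. Depth, and the undescribed source file named for replicate 1 and not for replicate 2, were not tested.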

How the results depend on the processing

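Of the tests here, the mean in place of the median and the exon pairs matched on GC and free of repeats were chosen only after the results had been seen. Of the alternative values of main results, 91 kept their direction and their side of the threshold, stayed within 1.5 times as counts or moved by less than the spread between replicates, chromosomes or genes, 14 moved further and 2 newly passed a threshold. With a −log10 q of at least 2 the Pearson r between replicates was 0.988, equal to the main value after rounding but outside its narrow interval over genes, and with genes of at least 5 kb r was 0.992 and rho 0.981, where the alternative itself leaves out short genes. The mean in place of the median put 10 lists above and 14 below random lists, against 6 and 0 with the median, since many medians are 0, and gave 5.33% for X-linked genes (permutation p = 0.0002). The X-linked median was 0 without either replicate, with a permutation p of 0.045 without replicate 2, where the median of random lists lay above 0. Domains numbered 59836 with gaps of up to 500 bp (median 0.923 kb, longest 102.8 kb) and 17883 with gaps of up to 5 kb (median 4.76 kb, longest 200.5 kb), by construction of the merging. Leaving out a replicate gave domain medians from 1.34 to 1.63 kb and longest domains from 130.0 to 154.6 kb; the cause was not tested.

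Genomic classes, position along the gene and the share of X-linked genes kept their calls under each alternative run for them. Covered genes numbered from 7008 to 9327 over the alternatives, against which the circular shifts were not run again. The exon ratio kept its call with windows 1000 bp away (log2 0.59), a −log10 q of at least 2 and each replicate alone, but lost it in pairs matched on GC and free of repeats (log2 −0.000286, exact p = 0.995). For single lists, 138 results of Fisher's exact test were the same and 2 were not, for neurons (13 covered, adjusted p = 0.062) and glia (2 covered, 0.075) without replicate 1. Small counts of covered members moved by over 1.5 times with pooled peaks, to 4 midbrain factors, 10 axon guidance, 2 microglial and blood and 1 olfactory receptor genes, and midbrain factors also numbered 2 without the first 1 kb of each gene, with no change of call. For medians, 163 permutation results were the same and 5 newly passed: cell cycle and housekeeping genes passed with pooled peaks (adjusted permutation p = 0.03 and 0.048) and with unmatched lists (0.012 and 0.021), and housekeeping without replicate 2 (0.035). Depth limits what a missing peak means: read numbers are unknown, so a gene at 0 had no called peak at this depth.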

Other observations

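All values in this part were chosen for description after the main results had been seen. Of the 83 covered non-coding genes, a few with familiar names are given as examples, and no test was made of what these 83 genes have in common. Meg3, the maternally expressed RNA of the Dlk1 region (chromosome 12, 109541001–109571726), had 59.8% of its 30.7 kb inside replicated peaks (50.2% and 45.4% in replicates 1 and 2), and Mirg, in the same imprinted region (109729764–109749460), had 64.3% (54.0% and 50.6%). Rmst, a long RNA linked to neuronal differentiation (chromosome 10, 92071037–92165170), had 28.5% (25.03% and 23.2%). The microRNA host gene Mir9-3hg had 15.1% (13.3% and 9.43%, under the 10% mark in replicate 2) and Mir124-2hg had 12.3% (10.8% and 11.1%). Ftx, from the X-inactivation centre (chromosome X, 103560907–103623790), had 13.4% (11.5% and 12.8%).

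Genes with more exons were covered more often. Of 868 genes with 1 exon 10.5% were covered (12.1% and 9.79% in the replicates), of 5854 genes with 2 to 4 exons 23.6%, of 6503 genes with 5 to 9 exons 41.5%, and of 7724 genes with 10 or more 54.2% (54.5% and 51.9%). Without olfactory receptor genes the share was 11.2% for 1 exon and 28.2% for 2 to 4 exons. Gene length rises with exon number (medians 2.02, 7.34, 17.2 and 44.5 kb), and the pair was not separated.

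The mark ran past the annotated 3′ ends of covered genes and hardly before their starts. In the 5 kb downstream of 3760 covered genes with no other coding gene there, the mean share inside replicated peaks was 20.1% (19.0% and 16.5% in the replicates). In the 5 kb upstream of 4529 such genes it was 0.720% (0.757% and 0.580%).

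Of the merged domains, 297 lay at least 5 kb from any gene in the annotation, with a median length of 0.416 kb, and 5 of them were at least 5 kb long. The longest was at 91222078–91229934 on chromosome 4 (7.86 kb; 71.3% and 71.4% of bases inside peaks in the replicates) and falls inside the RefSeq model of Elavl2, and the next, at 104581026–104588320 on chromosome 5 (7.29 kb; 68.5% and 60.9%), inside the RefSeq model of Zfp33b. The others, at 85618237–85625496 on chromosome 8 (7.26 kb), 62066272–62071918 on chromosome 7 (5.65 kb) and 83994917–84000075 on chromosome 6 (5.16 kb), overlapped no gene of either annotation.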
